A study of Mus musculus with 15 samples.

How the data were processed

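RNA was sequenced from the livers of 15 mice in 5 groups of 3, with 1 library per animal. Per the labels' protocols, total RNA was isolated with TRIzol and chloroform, and polyadenylated RNA was selected for library construction. The submitters' processing notes name Trim Galore 0.6.10, Bowtie 1.3.1, STAR 2.7.10b and featureCounts 2.0.1 with mouse build mm39, and they do not state the role of Bowtie. Per the file headers, the deposited counts are reads in exons summed per gene by featureCounts, without strand and with each read counted for every gene that it overlaps. The summed exon length of each gene in bases stands beside the deposited counts. Because of these settings, values of overlapping genes share reads, and values of close gene copies (the Mup, Sult2a, Cyp2a, Cyp2b, Cyp2c, Cyp3a, Cyp4a and Saa families) are uncertain. Overlaps of exons with another gene reach 11.2% of length for Aldh1a1, 7.81% for Ddit3, 6.71% for Abcc3, 5.17% for Fitm2 and 4.92% for Stat2 among genes named below, besides Stk25, Fdft1 and Nr1d1. A second deposited table holds TPM, and 12 of its columns equal TPM recomputed from the counts and exon lengths within 0.001. The names of 3 further TPM columns do not tie them to a library, and these columns were not used.

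Total counts per library ran from 3873903 to 9797743 over 26264 genes, of which 6882 had no count in any library and 0 lay on the mitochondrial chromosome. Libraries were assigned to groups by their labels alone. Genes with enough counts by filterByExpr were kept, which left 13189 genes. Counts were scaled by TMM and fitted with a negative binomial model in 1 fit of all 15 libraries, with edgeR 4.0.16 in R 4.3.3 and its robust quasi-likelihood test. The common biological coefficient of variation was 0.134. In each of 6 comparisons, adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05. They measure the spread between these samples only. Levels are TMM-scaled CPM, and fitted log2 fold changes use edgeR's prior count. Where a group had no count of a gene, its floor was set at 3 counts over the whole group and the fold is given as a lower bound, which covers counting error only. Overlaps between exons were found with bedtools 2.31.1. The GC content of a gene is that of its longest transcript in GENCODE vM21, matched by symbol.

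Before the data were examined, 39 gene lists were fixed from general knowledge of liver pathways, stress responses and cell types, and 35 of them had at least 5 tested genes. Each was tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of 1 comparison. Camera with an estimated correlation and fry were run beside it. Camera compares a list with all other genes, whereas fry asks whether the genes of the list moved, on balance, one way. Counts "adjusted over the list alone" use only the p-values of the list's own genes.

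Genes are named by a rule that was also fixed before the data were examined. A named gene was called, averaged at least 1 CPM over the 6 libraries compared, showed no overlap between the groups and has no predicted or clone-based name. From these, the 10 largest rises and 10 largest falls of each comparison could be named (5 and 5 for HFD-338 against HFD-NS and HFD-337 against HFD-Res), with up to 2 called members per direction of each list. Stk25, Stk24 and Stk26 in HFD-337, HFD-338 and HFD-Res, and Thrb, Dio1, Thrsp, Me1 and Cyp7a1 in HFD-Res, are named whatever their result.

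The procedure was tested on simulated counts with 200 genes changed by known folds. Over the 6 comparisons it recovered 61.2% to 74.6% of genes changed 2-fold and 23.9% to 35.8% of those changed 1.5-fold, and 2.24% to 7.03% of its calls were false. All groups otherwise had the same means, and counts were drawn from the fitted model. These rates may therefore not hold in the real comparisons, where many more genes were called. Camera called 0 lists in the simulated counts, with at most 2 at an unadjusted p under 0.05 in a comparison. Genes were drawn independently of each other, so this cannot show how often camera calls lists whose genes vary together.

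The alternatives were RLE size factors, no low-count filter, DESeq2 1.42.0, limma-voom with quality weights, a fit of only the 2 groups compared, the deposited TPM and leaving out each library in turn. TPM recomputed from the counts (limma on log2 of TPM plus 1, for genes with a TPM of at least 1 in 3 libraries) was added after the data had been seen. To judge counts of genes shared by comparisons that use the same HFD-NS libraries, 20 data sets were simulated in which HFD-337, HFD-338 and HFD-Res equal HFD-NS and only SD-NS differs.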

Results

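Liver gene expression was measured by RNA sequencing of polyadenylated RNA in 15 mice. The series describes a high-fat diet model of metabolic dysfunction-associated steatotic liver disease, treated with resmetirom, an agonist of thyroid hormone receptor beta, or by knockdown of STK25, a protein kinase, with the antisense agent Gc337. The labels give 5 groups of 3 mice each: SD-NS, HFD-NS, HFD-338, HFD-337 and HFD-Res. The labels do not spell out SD or NS, nor the number in HFD-338. Libraries held 8490747, 5893454 and 3873903 counts in SD-NS and 8762163, 8030651 and 9797743 in HFD-NS. They held 7961529, 7079830 and 7100274 counts in HFD-338, 4681937, 8995337 and 5060839 in HFD-337, and 4637933, 4173224 and 6814824 in HFD-Res. Values after ± are SDs over 3 libraries per group.

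Stk25, the gene targeted in the series (chromosome 1, 93548473 to 93563449 in mm39), was lower in every library of HFD-337 and HFD-338 than in any other library. Its level was 50.6, 53.3 and 47.8 CPM in SD-NS replicates 6, 7 and 8, and 48.6, 43.7 and 47.3 in HFD-NS replicates 12, 13 and 16. In HFD-338 it was 22.0, 21.9 and 20.6 CPM (replicates 17, 18 and 19), in HFD-337 19.1, 18.8 and 14.6 (replicates 23, 26 and 27), and in HFD-Res 46.9, 37.7 and 41.3 (replicates 29, 30 and 34). The mean was 37.6% of HFD-NS in HFD-337 (log2 fold change -1.40, SE 0.115, adjusted p = 3.8e-08) and 46.2% in HFD-338 (log2 fold change -1.11, SE 0.11, adjusted p = 6.41e-07). In HFD-Res it was 90.2% of HFD-NS (log2 fold change -0.15, SE 0.108, adjusted p = 0.421), a difference that did not pass the test. HFD-337 was lower than HFD-338 by a log2 fold change of -0.29 (SE 0.119, adjusted p = 0.045), a call that was lost without HFD-338 replicate 17 (adjusted p = 0.102), HFD-338 replicate 18 (0.0776) or HFD-337 replicate 27 (0.161). It was also lost with no low-count filter (0.0686), with limma-voom (0.0655) and in a fit of the 2 groups alone (0.09). Exons of Stk25 overlap those of Farp2 over 23.1% of their length, and their reads cannot be separated without strand.

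Stk24, the closest paralog of Stk25 (chromosome 14, 121523753 to 121616642), averaged 63.9% of HFD-NS in HFD-337 (log2 fold change -0.63, SE 0.139, adjusted p = 0.00103) and 97.3% in HFD-338 (log2 fold change -0.04, SE 0.13, adjusted p = 0.846). The direct difference between HFD-337 and HFD-338 passed the test (log2 fold change -0.60, SE 0.14, adjusted p = 0.00137). HFD-Res was at 90.4% of HFD-NS (log2 fold change -0.14, adjusted p = 0.565). Genes with a longer genomic span fell more often in HFD-337, as given below. Of 8062 genes spanning 10 to 100 kb, as Stk24 does, 1985 fell and 1663 rose there. Of 1028 genes spanning 100 to 200 kb, 417 fell and 94 rose. Whether the fall of Stk24 belongs to this trend was not tested. The other paralog, Stk26, was near the floor, at 0.393 CPM in HFD-NS, 0.276 in HFD-337, 1.72 in HFD-338 and 0.664 in HFD-Res, and was not tested. A list of Stk25, its paralogs and partners in the STRIPAK phosphatase complex had 13 tested members. In HFD-337 against HFD-NS 5 of them fell and 2 rose, and as a list they did not pass (camera adjusted p = 0.163). Slmap, a STRIPAK subunit, was among the falls (log2 fold change -0.71, adjusted p = 2.04e-05).

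**Figure D1:**
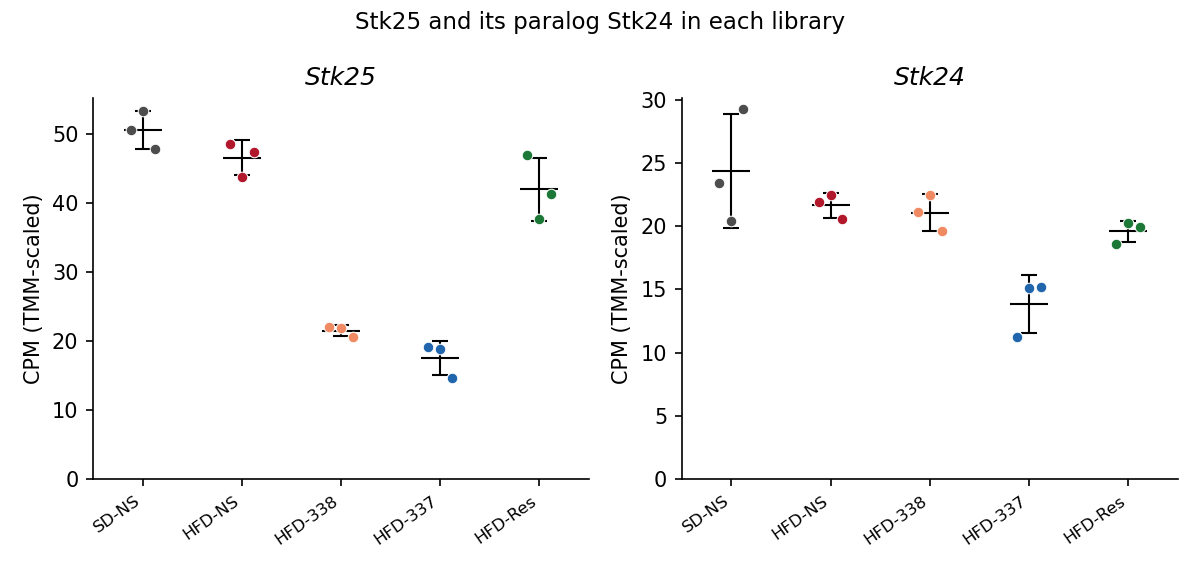
Level of Stk25 and Stk24 in CPM in each of the 15 libraries, by group, with the mean and SD of 3 libraries. Stk25 lies between 14.6 and 22.0 CPM in HFD-337 and HFD-338 and between 37.7 and 53.3 CPM in the other groups.

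HFD-NS was compared with SD-NS to ask how livers of the high-fat diet group differed from those of the SD group. Genes called here are said below to change with the diet. Whether the groups also differed in feeding state or time of sampling was not tested, and such differences cannot be told apart from diet. Ehhadh, a peroxisomal enzyme of fatty acid oxidation (chromosome 16, 21580035 to 21606584), averaged 680 ± 105 CPM in HFD-NS and 6762 ± 413 in SD-NS (log2 fold change -3.31, SE 0.159, adjusted p = 2.18e-10). Pdk4, a kinase that restrains pyruvate oxidation, averaged 22.8 ± 10.7 CPM in HFD-NS and 253 ± 12.3 in SD-NS (log2 fold change -3.48, SE 0.374, adjusted p = 7.34e-05). Lepr, the leptin receptor, averaged 4.45 ± 1.51 CPM in HFD-NS and 163 ± 54.9 in SD-NS (log2 fold change -5.20, SE 0.358, adjusted p = 1.65e-06). On the other side, Nr1d1, a repressor of the circadian clock, averaged 62.3 ± 10.9 CPM in HFD-NS and 9.72 ± 3.77 in SD-NS (log2 fold change 2.75, SE 0.222, adjusted p = 7.66e-07). The chemokine gene Cxcl10 averaged 17.1 ± 3.15 CPM in HFD-NS and 2.92 ± 0.580 in SD-NS (log2 fold change 2.49, SE 0.247, adjusted p = 1.33e-06). Cpne5, a calcium-binding protein gene, had no count in HFD-NS and 3.03 ± 0.742 CPM in SD-NS, at least 26.4-fold lower. Exons of Nr1d1 overlap those of Thra over 9.51% of their length. In all, 1589 genes rose and 2122 fell of 13189 tested, and 884 of them changed at least 2-fold (592 rises and 292 falls). The balance depends on the setting: 1988 rose and 1112 fell with recomputed TPM, and 1722 rose and 1511 fell with no low-count filter.

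Fatty acid oxidation genes and PPAR alpha targets fell together in HFD-NS, 25 of 32 with 2 rises. The list passed camera but not with correlation estimated (camera adjusted p = 3.91e-14, and adjusted p = 0.442 with an estimated correlation). Hadh, a mitochondrial enzyme of the same pathway, was 1 of the rises (log2 fold change 0.65, adjusted p = 0.000493). Cholesterol synthesis and uptake genes rose, 15 of 25 with 1 fall (camera adjusted p = 2.46e-09, and adjusted p = 0.52 with an estimated correlation). Among them was Nsdhl, an enzyme of sterol demethylation (log2 fold change 1.38, adjusted p = 1.8e-06). Interferon-stimulated genes rose, 22 of 33 with 0 falls (camera adjusted p = 1.49e-10, and adjusted p = 0.52 with an estimated correlation). Counts adjusted over the list alone were 25 falls for oxidation genes, 16 rises for cholesterol genes and 24 rises for interferon-stimulated genes. Genes of pericentral hepatocytes rose, 9 of 20 with 0 falls (camera adjusted p = 2.52e-05, and adjusted p = 0.442 with an estimated correlation). One such gene was Aldh1a1, a retinaldehyde dehydrogenase (log2 fold change 1.29, adjusted p = 1.13e-07).

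Inflammatory cytokines and chemokines rose in HFD-NS, 10 of 23 with 1 fall (camera adjusted p = 4.57e-06, and adjusted p = 0.52 with an estimated correlation). Markers of monocyte-derived and lipid-associated macrophages rose, 7 of 15 with 1 fall (camera adjusted p = 0.000985, and adjusted p = 0.784 with an estimated correlation). Mmp12, a macrophage elastase, was among them (log2 fold change 3.92, adjusted p = 8.67e-05), and Cd9 was the marker that fell (log2 fold change -1.36, adjusted p = 4.04e-06). Fibrosis and extracellular matrix genes rose, 11 of 32 with 2 falls (camera adjusted p = 0.000535, and adjusted p = 0.822 with an estimated correlation). Col3a1, a fibrillar collagen, averaged 46.0 ± 15.4 CPM in HFD-NS and 9.33 ± 1.36 in SD-NS (log2 fold change 2.29, SE 0.503, adjusted p = 0.00689). Unfolded protein and integrated stress response genes rose, 14 of 23 with 2 falls (camera adjusted p = 0.000227, and adjusted p = 0.784 with an estimated correlation). Ddit3 was among the rises (log2 fold change 1.25, adjusted p = 0.000495), and Atf5 fell (log2 fold change -1.07, adjusted p = 3.59e-06). The fibrosis and stress lists did not pass fry (adjusted p = 0.0907 and 0.0509). Acute phase genes rose in 6 cases of 27 and fell in 1 (camera adjusted p = 0.0316, and adjusted p = 0.83 with an estimated correlation). Their call was lost without SD-NS replicate 6 (0.198) or HFD-NS replicate 13 (0.217) and with fry (0.182).

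Of the other 26 lists tested, none passed camera in this comparison, although members of several moved in both directions. Camera tests for a common direction, so not passing does not mean that such a list was unchanged. Of all genes tested, 28.1% were called. Circadian clock genes rose in 11 cases of 20 and fell in 5 (camera adjusted p = 0.0763), with Clock itself lower (log2 fold change -0.92, adjusted p = 3.59e-06). Lipid droplet genes rose in 9 cases of 26 and fell in 10 (camera adjusted p = 0.494). Dgat2, an enzyme of triglyceride synthesis, rose (log2 fold change 1.08, adjusted p = 1.21e-05) and Plin2, a droplet coat protein, fell (log2 fold change -1.35, adjusted p = 2.39e-05). Markers of T and NK cells rose in 2 cases of 6 (camera adjusted p = 0.494). By camera 9 lists were called. With an estimated correlation 0 were, and 2 had an unadjusted p under 0.05.

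HFD-337 was compared with HFD-NS to ask how livers of the group labelled with the number of the agent against Stk25 differed. The labels name no group as a control for this agent. Changes in this comparison therefore cannot be assigned to lower Stk25 rather than to the agent. HFD-338, where Stk25 was lower too, differed from HFD-337 in 7701 of 13189 genes. Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, averaged 131 ± 30.6 CPM in HFD-337 and 449 ± 26.0 in HFD-NS (log2 fold change -1.77, SE 0.128, adjusted p = 1.03e-08). Clybl, a mitochondrial citramalyl-CoA lyase (chromosome 14, 122419106 to 122639646), averaged 4.01 ± 1.89 CPM in HFD-337 and 45.5 ± 2.03 in HFD-NS (log2 fold change -3.44, SE 0.198, adjusted p = 1.89e-09). It spans over 200 kb, and genes of that span fell more often in this group, as given below. Apob, the structural protein of very-low-density lipoprotein, averaged 2940 ± 294 CPM in HFD-337 and 7192 ± 469 in HFD-NS (log2 fold change -1.29, SE 0.119, adjusted p = 1.44e-07). Lyve1, a hyaluronan receptor of liver sinusoidal endothelium (chromosome 7, 110449814 to 110462160), averaged 3.73 ± 0.846 CPM in HFD-337 and 21.7 ± 2.79 in HFD-NS (log2 fold change -2.53, SE 0.225, adjusted p = 9.05e-08). Stat2, a transducer of type I interferon signals, rose (log2 fold change 1.14, SE 0.0924, adjusted p = 3.64e-08). Tff3, a secreted trefoil peptide, averaged 6.56 ± 2.51 CPM in HFD-337 and 0.388 ± 0.0958 in HFD-NS (log2 fold change 3.99, SE 0.457, adjusted p = 1.41e-06). In all, 3214 genes rose and 3006 fell, and 1874 of them changed at least 2-fold. With recomputed TPM 2244 rose and 3613 fell.

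Fatty acid oxidation genes and PPAR alpha targets fell in HFD-337, 27 of 32 with 1 rise (camera adjusted p = 2.44e-10, and adjusted p = 0.713 with an estimated correlation). Ehhadh, already low in HFD-NS, averaged 165 ± 34.8 CPM in HFD-337 and 680 ± 105 in HFD-NS (log2 fold change -2.04, SE 0.152, adjusted p = 1.48e-08). Lipid droplet, fat uptake and storage genes fell, 17 of 26 with 3 rises (camera adjusted p = 0.00384, and adjusted p = 0.713 with an estimated correlation). Among them were Fitm2, which packages triglyceride into droplets (log2 fold change -1.71, adjusted p = 8.32e-07), and Pnpla2, a triglyceride lipase (log2 fold change -0.80, adjusted p = 4.44e-06). Interferon-stimulated genes rose, 27 of 33 with 1 fall (camera adjusted p = 7.37e-10, and adjusted p = 0.713 with an estimated correlation), including Xaf1 (log2 fold change 1.99, adjusted p = 1.5e-07). Counts adjusted over the list alone were 28 falls for oxidation genes, 17 falls for lipid droplet genes and 28 rises for interferon-stimulated genes.

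Thyroid hormone receptor targets fell in 8 cases of 24 in HFD-337 and rose in 1 (camera adjusted p = 0.0338, and adjusted p = 0.475 with an estimated correlation). Me1, which encodes malic enzyme, fell (log2 fold change -1.99, adjusted p = 3.47e-07) and Apoa1, the main protein of high-density lipoprotein, rose (log2 fold change 0.76, adjusted p = 5.77e-05). Xenobiotic response genes fell in 12 cases of 27 and rose in 2 (camera adjusted p = 0.0338, and adjusted p = 0.756 with an estimated correlation). Female-biased liver genes fell in 10 cases of 20 and rose in 1 (camera adjusted p = 0.0338, and adjusted p = 0.756 with an estimated correlation). Glucose and glycogen genes fell in 8 cases of 23 and rose in 2 (camera adjusted p = 0.0496, and adjusted p = 0.713 with an estimated correlation). Pcx, which makes oxaloacetate from pyruvate, was among these falls (log2 fold change -1.32, adjusted p = 2.14e-09).

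Markers of liver sinusoidal endothelium fell in HFD-337, 13 of 15 with 0 rises, or 14 falls adjusted over the list alone (camera adjusted p = 8.03e-08, and adjusted p = 0.713 with an estimated correlation). Oit3 averaged 6.86 ± 0.843 CPM in HFD-337 and 24.3 ± 0.248 in HFD-NS (log2 fold change -1.84, SE 0.205, adjusted p = 1.09e-06). All 15 of these markers were at 1 CPM or more in SD-NS liver and 0 are on another list. Markers of Kupffer cells fell in 6 cases of 15 (camera adjusted p = 0.0338, and adjusted p = 0.874 with an estimated correlation), with the mannose receptor gene Mrc1 among them (log2 fold change -1.84, adjusted p = 9.8e-06). Stellate cell markers fell in 6 cases of 14 and rose in 1 (camera adjusted p = 0.128), and fibrosis genes fell in 10 cases of 32 and rose in 2 (camera adjusted p = 0.083). Neither passed as a list, though Dcn, a collagen-binding proteoglycan, fell (log2 fold change -1.29, adjusted p = 0.000207). Respiratory chain genes moved both ways, with 16 rises and 9 falls of 35 (camera adjusted p = 0.0871). Uqcrq, a subunit of complex III, rose (log2 fold change 1.15, adjusted p = 1.98e-07) and Sdha, a subunit of complex II, fell (log2 fold change -0.75, adjusted p = 5.98e-06). In the same libraries, genes with a long genomic span were lower. Of 539 genes spanning at least 200 kb, 26.2% fell at least 2-fold, against 3.92% of 3544 genes spanning under 10 kb. Of the latter, 1417 rose and 350 fell at any size of change. Whether the rises of respiratory chain genes belong to this trend was not tested. The haemoglobin gene Hbb-bs lay at 536, 199 and 93.2 CPM in replicates 23, 26 and 27, and red blood cell markers did not pass as a list (camera adjusted p = 0.326).

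Of the 9 lists called by camera in HFD-337, 0 passed with an estimated correlation, by which 2 had an unadjusted p under 0.05. Without HFD-337 replicate 27, 4 lists were called by camera. The lists of thyroid hormone receptor targets, glucose genes, female-biased genes and Kupffer markers lost their calls without this replicate (adjusted p = 0.0605 each), and the xenobiotic list did so at 0.0764. The Kupffer and xenobiotic lists also lost it without HFD-NS replicate 13 (0.0502 each), the Kupffer list without HFD-337 replicate 26 (0.0693), and the glucose list with RLE size factors (0.0503) or without HFD-NS replicate 16 or HFD-337 replicate 23 (0.0733 each).

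**Figure D2:**
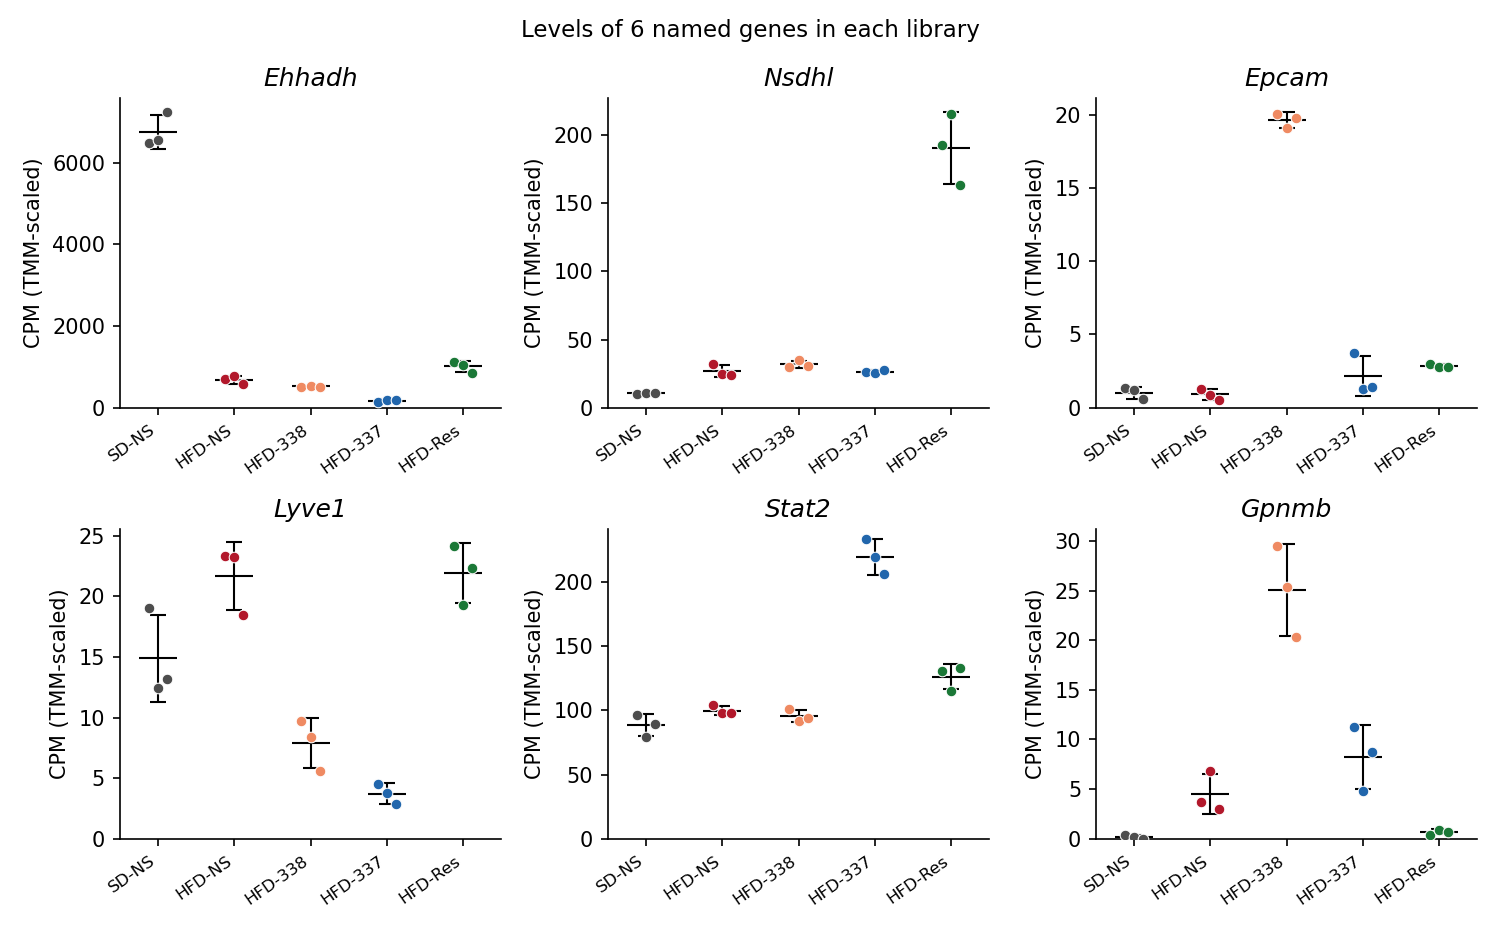
Level of Ehhadh, Nsdhl, Epcam, Lyve1, Stat2 and Gpnmb in CPM in each of the 15 libraries, by group, with the mean and SD of 3 libraries. Epcam averages 19.6 CPM in HFD-338, Nsdhl 191 CPM in HFD-Res and Lyve1 3.73 CPM in HFD-337.

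HFD-338 was compared with HFD-NS to ask how this second group with lower Stk25 differed from the high-fat diet group. Epcam, an adhesion protein of bile duct epithelium (chromosome 17, 87943407 to 87958555), averaged 19.6 ± 0.522 CPM in HFD-338 and 0.894 ± 0.379 in HFD-NS (log2 fold change 4.45, SE 0.312, adjusted p = 1.77e-08). Spink1, a secreted inhibitor of trypsin (chromosome 18, 43861134 to 43870302), averaged 36.5 ± 8.51 CPM in HFD-338 and 0.0803 ± 0.0696 in HFD-NS (log2 fold change 8.58, SE 0.527, adjusted p = 1.57e-08). Mmp2, a matrix gelatinase, averaged 26.8 ± 4.67 CPM in HFD-338 and 2.15 ± 0.700 in HFD-NS (log2 fold change 3.65, SE 0.269, adjusted p = 2.62e-08). Cenpf, a kinetochore protein of dividing cells, averaged 8.25 ± 1.43 CPM in HFD-338 and 0.690 ± 0.110 in HFD-NS (log2 fold change 3.55, SE 0.371, adjusted p = 1.28e-06). Among the falls, Glul, the glutamine synthetase of pericentral hepatocytes, averaged 455 ± 104 CPM in HFD-338 and 1746 ± 116 in HFD-NS (log2 fold change -1.94, SE 0.155, adjusted p = 5.56e-08). Fabp1, the liver fatty acid-binding protein, averaged 2472 ± 298 CPM in HFD-338 and 6367 ± 1020 in HFD-NS (log2 fold change -1.37, SE 0.13, adjusted p = 4.11e-07). Folh1 and Fbn2 had no count in HFD-NS and were at least 24.8-fold and 24.7-fold higher in HFD-338. In all, 2490 genes rose and 2357 fell, and 1784 of them changed at least 2-fold (1381 rises and 403 falls). With recomputed TPM 2792 rose and 1377 fell.

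Cholangiocyte markers rose in HFD-338, all 10 tested (camera adjusted p = 3.36e-13, and adjusted p = 0.0343 with an estimated correlation). Cdh1, which encodes E-cadherin, averaged 97.2 ± 7.94 CPM in HFD-338 and 7.62 ± 2.81 in HFD-NS (log2 fold change 3.67, SE 0.286, adjusted p = 1.51e-06). Of the 12 genes on this list, 6 were at 1 CPM or more in SD-NS liver and 1 is on another list. Fibrosis and extracellular matrix genes rose, 24 of 32 with 1 fall (camera adjusted p = 1.38e-12, and adjusted p = 0.248 with an estimated correlation). Col5a2, a fibrillar collagen, was among the rises (log2 fold change 2.64, adjusted p = 3.94e-07), and Fn1, fibronectin, was the fall (log2 fold change -0.49, adjusted p = 0.00145). Cell cycle genes rose, 21 of 26 with 0 falls (camera adjusted p = 1.8e-11, and adjusted p = 0.166 with an estimated correlation). Mcm6, a replication helicase subunit, was among them (log2 fold change 2.06, adjusted p = 2.22e-06). Targets of p53 rose, 14 of 19 with 1 fall (camera adjusted p = 6.02e-07, and adjusted p = 0.166 with an estimated correlation), including Phlda3 (log2 fold change 3.27, adjusted p = 2.85e-06). Adjusted over the list alone, 10 cholangiocyte, 25 fibrosis, 23 cell cycle and 15 p53 target genes rose.

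Markers of monocyte-derived and lipid-associated macrophages rose in HFD-338, 12 of 15 with 0 falls (camera adjusted p = 2.94e-06, and adjusted p = 0.248 with an estimated correlation). Gpnmb, a marker of lipid-laden macrophages, averaged 25.1 ± 4.63 CPM in HFD-338 and 4.51 ± 2.05 in HFD-NS (log2 fold change 2.49, SE 0.291, adjusted p = 7.04e-06), and Cd9 rose as well (log2 fold change 1.59, adjusted p = 3.18e-07). Of the 15 genes on this list, 8 were at 1 CPM or more in SD-NS liver and 3 are on another list. Interferon-stimulated genes rose, 18 of 33 with 0 falls (camera adjusted p = 6.02e-07, and adjusted p = 0.362 with an estimated correlation), including Oas1a, an antiviral enzyme (log2 fold change 2.59, adjusted p = 1.92e-06). Oxidative stress genes and NRF2 targets rose in 11 cases of 26 and fell in 5 (camera adjusted p = 0.0252, and adjusted p = 0.362 with an estimated correlation), with Nqo1, a quinone reductase, higher (log2 fold change 1.71, adjusted p = 1.85e-05). This call was lost without HFD-NS replicate 16 (0.0861) and with no low-count filter (0.0857). Markers of sinusoidal endothelium fell, 9 of 15 with 1 rise (camera adjusted p = 0.00114, and adjusted p = 0.412 with an estimated correlation), among them Lyve1 (log2 fold change -1.44, adjusted p = 1.49e-05).

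Several lists of hepatocyte metabolism moved down in HFD-338. Fatty acid oxidation genes and PPAR alpha targets fell, 29 of 32 with 0 rises (camera adjusted p = 2.81e-13, and adjusted p = 0.166 with an estimated correlation), among them Eci1, an enoyl-CoA isomerase (log2 fold change -0.89, adjusted p = 1.92e-06). Lipid droplet, fat uptake and storage genes fell, 18 of 26 (camera adjusted p = 1.55e-08, and adjusted p = 0.166 with an estimated correlation). Mgll, a monoglyceride lipase, was among these falls (log2 fold change -1.51, adjusted p = 1.93e-07), and Lpl, the lipoprotein lipase, was the 1 rise (log2 fold change 3.08, adjusted p = 0.00011). Respiratory chain genes fell in 26 cases of 35 with 0 rises (camera adjusted p = 9.1e-08, and adjusted p = 0.362 with an estimated correlation), including Sdhc (log2 fold change -0.73, adjusted p = 1.61e-05). Bile acid genes fell in 13 cases of 24 with 0 rises (camera adjusted p = 0.00018, and adjusted p = 0.248 with an estimated correlation), including Nr1h4, the bile acid receptor gene (log2 fold change -0.75, adjusted p = 1.22e-05). Fatty acid synthesis genes fell in 10 cases of 20 and rose in 3 (camera adjusted p = 0.00337, and adjusted p = 0.337 with an estimated correlation). Acacb, which makes malonyl-CoA at mitochondria, fell (log2 fold change -2.13, adjusted p = 1.23e-06), and Scd2, a desaturase, rose (log2 fold change 1.63, adjusted p = 9.05e-05). Adjusted over the list alone, 30 oxidation, 19 lipid droplet, 27 respiratory chain and 16 bile acid genes fell.

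Falls also passed as lists for lipoprotein genes, 7 of 20 with 1 rise (camera adjusted p = 0.0057, and adjusted p = 0.248 with an estimated correlation), and thyroid hormone receptor targets, 9 of 24 with 2 rises (camera adjusted p = 0.0252, and adjusted p = 0.166 with an estimated correlation). Periportal genes fell in 6 cases of 20 (camera adjusted p = 0.021, and adjusted p = 0.472 with an estimated correlation) and pericentral genes in 10 of 20 with 2 rises (camera adjusted p = 0.0315, and adjusted p = 0.362 with an estimated correlation). Glucose genes fell in 9 cases of 23 and rose in 1 (camera adjusted p = 0.0377, and adjusted p = 0.383 with an estimated correlation), and 9 of 23 unfolded protein response genes fell, with 1 rise (camera adjusted p = 0.0175, and adjusted p = 0.582 with an estimated correlation). Herpud1, a component of endoplasmic reticulum protein disposal, was among the last (log2 fold change -1.53, adjusted p = 8.45e-05). The pericentral call was lost without HFD-NS replicate 13 (0.0552), and the glucose call without HFD-NS replicate 16 (0.0881) or HFD-338 replicate 18 (0.0645). The unfolded protein call was lost without HFD-NS replicate 12 (0.056) or with fry (0.0722). By camera 19 lists were called, and 1 of them, the cholangiocyte list, passed with an estimated correlation.

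HFD-Res was compared with HFD-NS to ask how livers of the resmetirom group differed. The labels do not spell out NS, so changes here cannot be assigned to resmetirom rather than to the way it was given. Nsdhl (chromosome X, 71962127 to 72002134), which rose with the diet, averaged 191 ± 26.3 CPM in HFD-Res and 26.9 ± 4.24 in HFD-NS (log2 fold change 2.83, SE 0.12, adjusted p = 4.4e-12). Dio1, the type 1 deiodinase that activates thyroid hormone, averaged 679 ± 44.3 CPM in HFD-Res and 136 ± 10.6 in HFD-NS (log2 fold change 2.32, SE 0.269, adjusted p = 0.000102). Me1 averaged 380 ± 70.9 CPM in HFD-Res and 109 ± 16.6 in HFD-NS (log2 fold change 1.80, SE 0.166, adjusted p = 1.86e-06). Abcc3, an efflux transporter of conjugated bile acids, averaged 16.9 ± 2.71 CPM in HFD-Res and 342 ± 24.7 in HFD-NS (log2 fold change -4.35, SE 0.144, adjusted p = 1.15e-13). Nox4, an oxidase that makes hydrogen peroxide, averaged 4.61 ± 1.89 CPM in HFD-Res and 68.8 ± 9.46 in HFD-NS (log2 fold change -3.83, SE 0.306, adjusted p = 2.72e-06). Cux2, a transcription factor of female-pattern liver expression, averaged 19.7 ± 5.87 CPM in HFD-Res and 0.383 ± 0.335 in HFD-NS (log2 fold change 5.60, SE 0.46, adjusted p = 2.84e-07). In all, 820 genes rose and 889 fell, and 581 of them changed at least 2-fold. With limma-voom 951 rose and 923 fell. The total was 1709, and 1134 without HFD-Res replicate 34.

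Cholesterol synthesis and uptake genes rose in HFD-Res, 24 of 25 with 0 falls (camera adjusted p = 3.85e-115, and adjusted p = 0.000405 with an estimated correlation). Fdft1, the squalene synthase gene, shares 20.9% of its exon length with Ctsb and was among them (log2 fold change 2.62, adjusted p = 1.12e-10). Thyroid hormone receptor targets rose, 11 of 24 with 2 falls, or 15 rises adjusted over the list alone (camera adjusted p = 2.07e-12, and adjusted p = 0.00037 with an estimated correlation). Of these 24 targets 14 are also on another list. Thrsp, a lipogenic target, rose (log2 fold change 2.00, adjusted p = 0.004). In a fit of the 2 groups alone its log2 fold change was 1.99, but the call was lost (adjusted p = 0.0775). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, averaged 525 ± 246 CPM in HFD-Res and 198 ± 53.4 in HFD-NS (log2 fold change 1.41, SE 0.473, adjusted p = 0.0833). It did not pass, though it did without HFD-Res replicate 34 (adjusted p = 0.0354), with DESeq2 (0.026) and with limma-voom (0.0227). Thrb, the receptor gene itself, did not pass either (log2 fold change 0.32, adjusted p = 0.0923), except with limma-voom (0.0464). Fatty acid synthesis genes rose, 13 of 20 with 0 falls (camera adjusted p = 1.26e-12, and adjusted p = 0.019 with an estimated correlation), including the desaturase Fads2 (log2 fold change 0.95, adjusted p = 2.6e-06). Interferon-stimulated genes rose, 20 of 33 with 0 falls (camera adjusted p = 4.26e-13, and adjusted p = 0.188 with an estimated correlation), including Ifih1, a sensor of double-stranded RNA (log2 fold change 1.07, adjusted p = 3.63e-06).

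Female-biased liver genes rose in HFD-Res, 10 of 20 with 0 falls (camera adjusted p = 1.53e-20, and adjusted p = 0.019 with an estimated correlation). Sult2a1, a sulfotransferase of steroids and bile acids, averaged 321 ± 59.3 CPM in HFD-Res and 0.872 ± 0.515 in HFD-NS (log2 fold change 8.48, SE 0.232, adjusted p = 7.78e-14), a value that is uncertain because close copies share its sequence. Male-biased genes fell in 4 cases of 22 and rose in 1 (camera adjusted p = 0.086), which did not pass as a list. Genes of the growth hormone and IGF axis rose in 2 cases of 14 and fell in 1 (camera adjusted p = 0.0126, and adjusted p = 0.0802 with an estimated correlation), with Cux2 on both this and the female-biased list.

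Falls in HFD-Res covered several lists. Inflammatory genes fell in 5 cases of 23 (camera adjusted p = 0.000904, and adjusted p = 0.431 with an estimated correlation), with the chemokine gene Ccl2 among them (log2 fold change -2.38, adjusted p = 0.000799). Acute phase genes fell in 6 cases of 27 (camera adjusted p = 9.27e-05, and adjusted p = 0.53 with an estimated correlation), including Serpina3n (log2 fold change -0.92, adjusted p = 0.000718). Autophagy and lysosome genes fell in 8 cases of 26 (camera adjusted p = 0.00113, and adjusted p = 0.133 with an estimated correlation), including Hexa, a lysosomal hexosaminidase (log2 fold change -1.41, adjusted p = 1.33e-05). Glucose genes fell in 8 cases of 23 and rose in 1 (camera adjusted p = 0.000162, and adjusted p = 0.133 with an estimated correlation), the falls including Fbp1, an enzyme of gluconeogenesis (log2 fold change -1.28, adjusted p = 9.51e-06). Periportal genes fell in 9 cases of 20 and rose in 1 (camera adjusted p = 2.24e-05, and adjusted p = 0.235 with an estimated correlation), with Aldh1b1 among the falls (log2 fold change -2.02, adjusted p = 1.02e-05).

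Oxidative stress genes and NRF2 targets fell in 6 cases of 26 and rose in 1 (camera adjusted p = 0.000698, and adjusted p = 0.172 with an estimated correlation), the falls including catalase, Cat (log2 fold change -0.60, adjusted p = 0.000466). Lipid droplet genes fell in 7 cases of 26 and rose in 1 (camera adjusted p = 0.0067, and adjusted p = 0.53 with an estimated correlation), the falls including Hsd17b13 (log2 fold change -0.83, adjusted p = 6.4e-05). Adipose markers fell in 3 cases of 8 (camera adjusted p = 0.000316, and adjusted p = 0.0802 with an estimated correlation), including Car3 (log2 fold change -2.15, adjusted p = 5.57e-05). Of the 12 genes on the adipose list, 5 are on another list and 7 were at 1 CPM or more in SD-NS liver. Their fall can therefore not be assigned to adipose tissue. Markers of lipid-associated macrophages fell in 2 cases of 15 (camera adjusted p = 0.0267, and adjusted p = 0.759 with an estimated correlation), with Gpnmb at 0.692 ± 0.248 CPM in HFD-Res and 4.51 ± 2.05 in HFD-NS (log2 fold change -2.66, adjusted p = 0.00199). That list was not called without HFD-NS replicate 13 (0.165) or with fry (0.172). Hepatocyte genes fell in 4 cases of 16 and rose in 2 (camera adjusted p = 0.0474, and adjusted p = 0.759 with an estimated correlation). This call was lost without HFD-NS replicate 16 (0.0995), HFD-Res replicate 29 (0.0545) or HFD-Res replicate 30 (0.123) and with fry (0.0991). Fatty acid oxidation genes, 2 higher and 4 lower of 32 (camera adjusted p = 0.0961), and fibrosis genes, 0 called of 32 (camera adjusted p = 0.3), did not pass. By camera 16 lists were called, of which 4 passed with an estimated correlation.

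**Figure D3:**
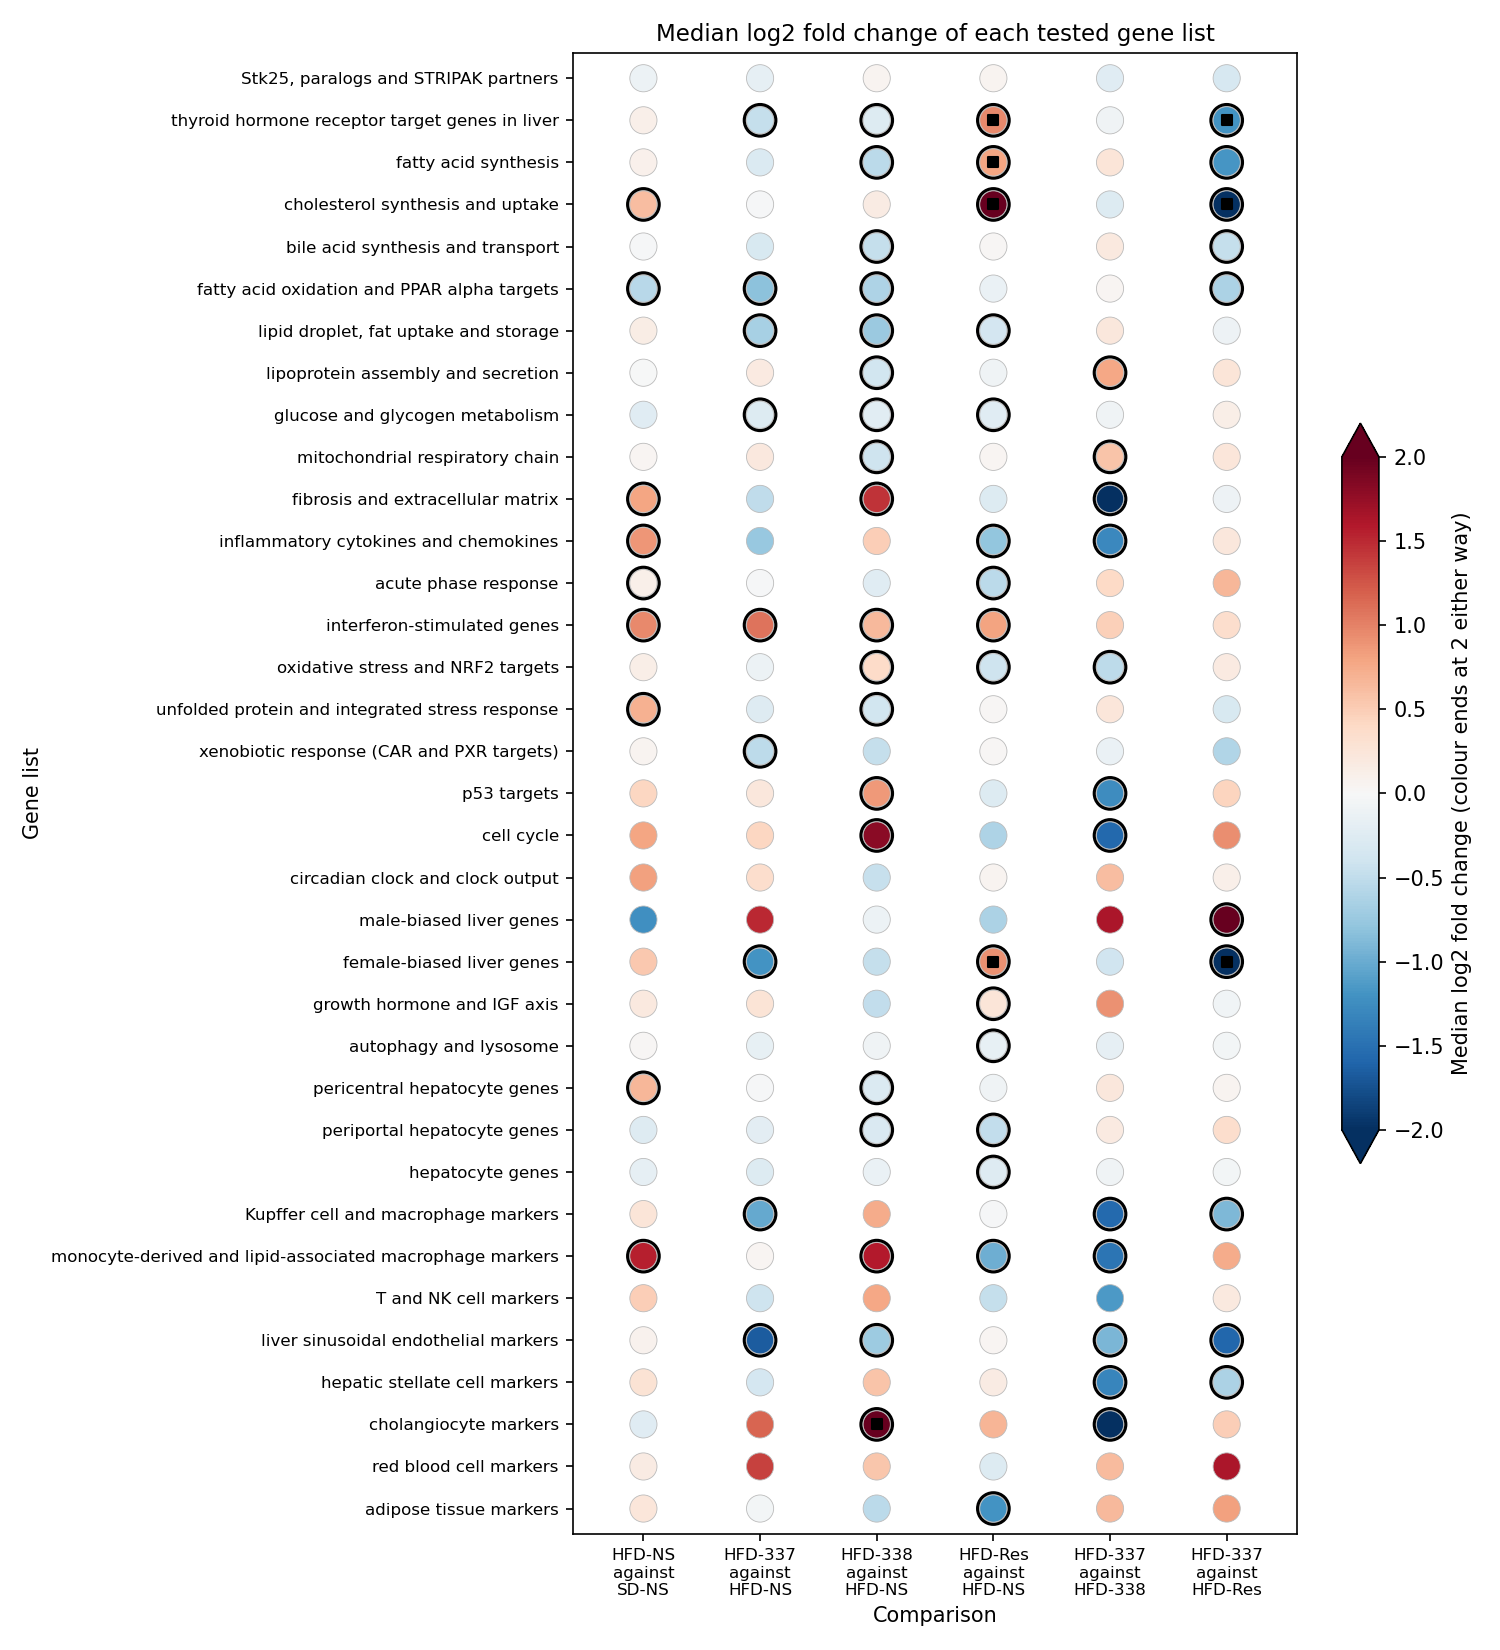
Median log2 fold change of each of 35 gene lists (lines) in the 6 comparisons (columns), as colour that is capped at 2 in either direction. A black ring marks a camera adjusted p under 0.05 and a black square an adjusted p under 0.05 with an estimated correlation, which 1 list reached in HFD-338 against HFD-NS, 4 lists in HFD-Res against HFD-NS and 3 lists in HFD-337 against HFD-Res.

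HFD-337 and HFD-338, the groups with lower Stk25, were compared directly to ask whether their livers differed. Mmp2 averaged 3.54 ± 1.21 CPM in HFD-337 and 26.8 ± 4.67 in HFD-338 (log2 fold change -2.96, SE 0.265, adjusted p = 7.22e-08). Gpc3, a proteoglycan of fetal liver, averaged 0.594 ± 0.210 CPM in HFD-337 and 44.2 ± 22.2 in HFD-338 (log2 fold change -6.19, SE 0.501, adjusted p = 2.56e-07). Fbn2, a fibrillin gene, had no count in HFD-337 and was at least 17.7-fold lower. Uqcrq averaged 527 ± 39.2 CPM in HFD-337 and 160 ± 21.2 in HFD-338 (log2 fold change 1.72, SE 0.112, adjusted p = 2.82e-09). Glul, which fell in HFD-338, averaged 1197 ± 237 CPM in HFD-337 and 455 ± 104 in HFD-338 (log2 fold change 1.40, SE 0.152, adjusted p = 6.01e-07). In all, 3794 genes were higher and 3907 lower in HFD-337, a near-even balance, and 3111 of them differed at least 2-fold (1125 higher and 1986 lower). This even balance depends on the setting: 2118 were higher and 5159 lower with deposited TPM, and 2194 and 5314 with recomputed TPM. With RLE size factors 3598 were higher and 4136 lower. The median of all genes here was -0.23 on the log2 scale with either TPM, against -0.000315 with TMM and -0.0375 with RLE size factors. TPM also brings another test and filter, so its shift cannot be put down to scaling alone. Values from TPM are read relative to this shift.

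Fibrosis and extracellular matrix genes were lower in HFD-337 than in HFD-338, 29 of 32 with 1 higher, the same counts as adjusted over the list alone (camera adjusted p = 1.44e-11, and adjusted p = 0.578 with an estimated correlation). Cholangiocyte markers were lower in 9 cases of 10 and higher in 1 (camera adjusted p = 0.000398, and adjusted p = 0.578 with an estimated correlation), the lower ones including Krt23, a keratin (log2 fold change -3.28, adjusted p = 1.66e-06). Cell cycle genes were lower in 20 cases of 26 and higher in 2 (camera adjusted p = 0.000289, and adjusted p = 0.602 with an estimated correlation), the lower ones including Cenpf (log2 fold change -2.66, adjusted p = 6.38e-06). Targets of p53 were lower in 13 cases of 19 and higher in 1 (camera adjusted p = 0.000398, and adjusted p = 0.578 with an estimated correlation), the lower ones including Ccng1 (log2 fold change -1.26, adjusted p = 1.12e-07). Inflammatory genes were lower in 13 cases of 23 and higher in 2 (camera adjusted p = 0.00972, and adjusted p = 0.642 with an estimated correlation), the lower ones including Tlr4, the receptor for lipopolysaccharide (log2 fold change -2.57, adjusted p = 1.73e-06). Oxidative stress genes and NRF2 targets were lower in 15 cases of 26 and higher in 3 (camera adjusted p = 0.0216, and adjusted p = 0.602 with an estimated correlation), the lower ones including Nqo1 (log2 fold change -2.38, adjusted p = 6.18e-07).

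Kupffer cell markers were lower in HFD-337 than in HFD-338 in 12 cases of 15 (camera adjusted p = 0.00277, and adjusted p = 0.642 with an estimated correlation), and all 15 were at 1 CPM or more in SD-NS liver. Adgre1, which encodes F4/80, was among them (log2 fold change -2.43, adjusted p = 2.53e-05). Markers of lipid-associated macrophages were lower in 12 cases of 15 (camera adjusted p = 0.00121, and adjusted p = 0.602 with an estimated correlation), such as Cd9 (log2 fold change -2.12, adjusted p = 1.49e-08). Stellate cell markers were lower in 9 cases of 14 and higher in 1 (camera adjusted p = 0.00956, and adjusted p = 0.642 with an estimated correlation), the lower ones including Reln (log2 fold change -1.34, adjusted p = 8.98e-05). Endothelial markers were lower in 10 cases of 15 and higher in 1 (camera adjusted p = 0.0288, and adjusted p = 0.728 with an estimated correlation), the lower ones including Pecam1 (log2 fold change -1.68, adjusted p = 5.11e-05). The endothelial call was lost without HFD-338 replicate 17 (0.104) or HFD-337 replicate 26 (0.0684). Here 29.9% of genes spanning at least 200 kb were lower by at least 2-fold, against 10.4% of those spanning under 10 kb.

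Respiratory chain genes were higher in HFD-337 than in HFD-338, 24 of 35 with 2 lower (camera adjusted p = 2.51e-08, and adjusted p = 0.602 with an estimated correlation). Cox5b, a subunit of complex IV, was among them (log2 fold change 1.40, adjusted p = 1.33e-08). Genes with a short genomic span were also higher here: of 3544 spanning under 10 kb, 1640 were higher and 582 lower. Whether the rise of the respiratory chain list belongs to this trend was not tested. Lipoprotein genes were higher in 13 cases of 20 and lower in 3 (camera adjusted p = 0.0044, and adjusted p = 0.578 with an estimated correlation). Lcat, which esterifies plasma cholesterol, was higher (log2 fold change 1.02, adjusted p = 9.65e-08) and Apob was lower (log2 fold change -1.16, adjusted p = 3.13e-07). Mup12, the named gene with the largest rise, is uncertain as 1 of many close copies. Its call was lost without HFD-337 replicate 27 (adjusted p = 0.0618), with limma-voom (0.107) and in a fit of the 2 groups alone (0.0537). By camera 12 lists were called. With an estimated correlation 0 were, and 1 had an unadjusted p under 0.05.

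HFD-337 and HFD-Res, the treatments named in the series, were also compared directly. Me1 averaged 27.1 ± 6.81 CPM in HFD-337 and 380 ± 70.9 in HFD-Res (log2 fold change -3.80, SE 0.186, adjusted p = 5.1e-10). Nsdhl averaged 26.4 ± 1.02 CPM in HFD-337 and 191 ± 26.3 in HFD-Res (log2 fold change -2.86, SE 0.122, adjusted p = 5.55e-12). Ehhadh averaged 165 ± 34.8 CPM in HFD-337 and 1011 ± 138 in HFD-Res (log2 fold change -2.61, SE 0.156, adjusted p = 5.1e-10). Lyve1 averaged 3.73 ± 0.846 CPM in HFD-337 and 22.0 ± 2.46 in HFD-Res (log2 fold change -2.55, SE 0.232, adjusted p = 8.47e-08). Abcc3 averaged 145 ± 27.0 CPM in HFD-337 and 16.9 ± 2.71 in HFD-Res (log2 fold change 3.11, SE 0.14, adjusted p = 1.11e-11). Gpnmb averaged 8.26 ± 3.22 CPM in HFD-337 and 0.692 ± 0.248 in HFD-Res (log2 fold change 3.49, SE 0.494, adjusted p = 1.93e-05). Cux2 had no count in HFD-337 and was at least 123-fold lower than in HFD-Res. In all, 3205 genes were higher and 3078 lower in HFD-337, and 2234 of them differed at least 2-fold. With deposited TPM 2329 were higher and 3583 lower, and with recomputed TPM 2440 and 3765.

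Cholesterol synthesis and uptake genes were lower in HFD-337 than in HFD-Res, 24 of 25 with 1 higher (camera adjusted p = 1.2e-42, and adjusted p = 0.0215 with an estimated correlation). The 1 exception was Ebp, a sterol isomerase (log2 fold change 0.63, adjusted p = 4.76e-05). Thyroid hormone receptor targets were lower in 18 cases of 24 and higher in 1 (camera adjusted p = 3.36e-10, and adjusted p = 0.000826 with an estimated correlation), the lower ones including Gpd2, a mitochondrial glycerol phosphate dehydrogenase (log2 fold change -2.06, adjusted p = 6.56e-10). Female-biased genes were lower in 15 cases of 20 (camera adjusted p = 2.86e-14, and adjusted p = 0.0435 with an estimated correlation). Fatty acid synthesis genes were lower in 15 cases of 20 and higher in 4 (camera adjusted p = 7.43e-08, and adjusted p = 0.0961 with an estimated correlation), the lower ones including Fads2 (log2 fold change -1.46, adjusted p = 3.83e-09). Fatty acid oxidation genes were lower in 24 cases of 32 and higher in 2 (camera adjusted p = 8.03e-07, and adjusted p = 0.537 with an estimated correlation), the lower ones including Etfdh (log2 fold change -1.80, adjusted p = 4.72e-09). Bile acid genes were lower in 13 cases of 24 and higher in 4 (camera adjusted p = 0.0134, and adjusted p = 0.607 with an estimated correlation), the lower ones including the phospholipid exporter gene Abcb4 (log2 fold change -1.42, adjusted p = 1.4e-08).

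Endothelial markers were lower in HFD-337 than in HFD-Res in 13 cases of 15 (camera adjusted p = 1.48e-07, and adjusted p = 0.537 with an estimated correlation), with Oit3 among them (log2 fold change -1.82, adjusted p = 1.49e-06). Kupffer markers were lower in 6 cases of 15 (camera adjusted p = 0.03, and adjusted p = 0.853 with an estimated correlation) and stellate markers in 7 of 14 (camera adjusted p = 0.0416, and adjusted p = 0.853 with an estimated correlation). Male-biased genes were higher in 12 cases of 22 and lower in 1 (camera adjusted p = 0.03, and adjusted p = 0.853 with an estimated correlation). Those 3 calls were lost without HFD-337 replicate 27 (0.0605, 0.119 and 0.1) and without HFD-Res replicate 29 (0.0755, 0.0755 and 0.0769). The Kupffer and stellate calls were also lost without HFD-337 replicate 26 (0.102 and 0.085), and the male-biased call with fry (0.062). In the same comparison 27.5% of genes spanning at least 200 kb were lower by at least 2-fold, against 5.22% of those spanning under 10 kb. By camera 10 lists were called, and 3 passed with an estimated correlation.

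To ask how far the differences between HFD-NS and SD-NS were moved back, genes called in that comparison were followed into HFD-337, HFD-338 and HFD-Res. These differences may have causes other than diet, as said above. Few fatty acid oxidation genes moved back in the groups with lower Stk25: of 25 that fell with the diet, 23 fell further and 1 rose in HFD-337, and 22 fell further and 0 rose in HFD-338. In HFD-Res 2 of the 25 rose and 2 fell further. The 2 oxidation genes that rose with the diet fell in HFD-337 and HFD-338. Of 9 lipid droplet genes that rose with the diet, 8 fell in HFD-337, 7 in HFD-338 and 4 in HFD-Res. Of 10 lipid droplet genes that fell with the diet, 8, 7 and 2 fell further, in that order. Of 11 fibrosis genes that rose with the diet, 3 fell in HFD-337, 0 in HFD-338 and 0 in HFD-Res, and 8 rose further in HFD-338. Of 22 interferon-stimulated genes that rose with the diet, 18 rose further in HFD-337, 13 in HFD-338 and 12 in HFD-Res. Of 15 cholesterol genes that rose, 14 rose further in HFD-Res, and all 6 autophagy and lysosome genes that rose with the diet fell in HFD-Res.

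Over all 3711 genes called in HFD-NS against SD-NS, 854 (23.0%) moved back in HFD-337, 973 (26.2%) in HFD-338 and 569 (15.3%) in HFD-Res. With independent calls, 879.3, 684.6 and 239.0 would have done so, a figure that leaves out the shared HFD-NS libraries. Simulated data in which the 3 groups equal HFD-NS gave at most 2, a figure that leaves out all real effects on them. In the other direction, 1238 genes moved further from SD-NS in HFD-337, 598 in HFD-338 and 237 in HFD-Res, where independent calls would give 870.9, 679.2 and 241.8. The number moved back fell to 550 without HFD-NS replicate 13 and 562 without SD-NS replicate 7 for HFD-337, and to 377 without HFD-NS replicate 16 or HFD-Res replicate 34 for HFD-Res. Both comparisons of each count use the same 3 HFD-NS libraries, which were too few to divide, so part of these counts may come from shared error. On the log2 scale over all genes, the covariance of the 2 changes was -0.0174 in HFD-337, -0.00737 in HFD-338 and -0.119 in HFD-Res, and -0.0328, -0.0318 and -0.0343 in the simulated data. The observed value thus lay above the simulated one by 0.0154 and 0.0244 in HFD-337 and HFD-338, and the difference was -0.085 in HFD-Res. These differences come without a spread. In HFD-338 they and the counts point opposite ways, since more genes moved back (973) than further away (598).

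HFD-337 and HFD-338 shared 1635 genes that changed in the same direction against HFD-NS (660 higher and 975 lower), where independent calls would give 1144, and 732 that changed in opposite directions. HFD-337 and HFD-Res shared 630 (282 higher and 348 lower), where independent calls would give 402.4, and 323 in opposite directions. The second overlap was 392 without HFD-Res replicate 34 and 415 without HFD-NS replicate 13, and the same HFD-NS libraries enter both sides. For both overlaps part of the excess may come from these libraries. The covariance of the changes was 0.203 for HFD-337 and HFD-338 and 0.081 for HFD-337 and HFD-Res, against 0.0331 and 0.033 in the simulated data.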

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

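Of the settings reported here, only TPM recomputed from the counts was chosen after the results had been seen. Some settings change more than 1 choice by construction: DESeq2 brings its own size factors and test, fits of 2 groups test other genes, and TPM brings another test and filter. With RLE size factors, no low-count filter, DESeq2, limma-voom with quality weights, only the 2 groups compared, and either form of TPM where it was run, the number of changed genes stayed within 1.5 times of the report's in all 6 comparisons. It ran from 3100 to 4260 in HFD-NS against SD-NS, 5342 to 6218 in HFD-337, 4169 to 5498 in HFD-338 and 1478 to 1874 in HFD-Res, each of these 3 against HFD-NS. It ran from 7030 to 7915 in HFD-337 against HFD-338 and from 5222 to 6233 in HFD-337 against HFD-Res. The deposited TPM was run only in the last 2 comparisons (7277 and 5912 genes), because none of the columns tied to a library is from HFD-NS.

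Leaving out each library in turn kept these counts within 1.5 times, except in HFD-Res against HFD-NS. There the count of 1709 ranged from 1134 (without HFD-Res replicate 34) to 1467. The other ranges were 2478 to 3278 in HFD-NS against SD-NS, 5289 to 5811 in HFD-337, 3614 to 4510 in HFD-338, 6817 to 7643 in HFD-337 against HFD-338 and 5392 to 5958 in HFD-337 against HFD-Res. A group left with 2 libraries lowers the power of the test by construction.

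The number of gene lists called depended most on how correlation between genes was treated. With camera and an estimated correlation, 0 lists were called in HFD-NS against SD-NS, 0 in HFD-337 against HFD-NS and 0 in HFD-337 against HFD-338, where 2, 2 and 1 had an unadjusted p under 0.05. It called 1 in HFD-338 against HFD-NS, 4 in HFD-Res against HFD-NS and 3 in HFD-337 against HFD-Res. Estimating the correlation makes the test more cautious where the genes of a list vary together within groups. With fry, which does not compare a list with other genes, 16 lists were called in HFD-337 against HFD-NS, 21 in HFD-337 against HFD-338 and 16 in HFD-337 against HFD-Res, beyond 1.5 times camera's 9, 12 and 10. With no low-count filter 14 lists were called in HFD-NS against SD-NS instead of 9, and the cause was not tested. Without 1 library the number in HFD-337 against HFD-NS ranged from 4 (without HFD-337 replicate 27) to 12, and the other 5 comparisons stayed within 1.5 times. No called list reversed its direction. Over all settings 643 list calls kept their direction and passed, and 107 kept it and no longer passed: 67 with an estimated correlation, 31 without 1 library, 7 with fry, 1 with RLE size factors and 1 with no low-count filter.

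Without 1 library, the number of genes moved back ranged from 550 (without HFD-NS replicate 13) to 925 for HFD-337, against 854 with all libraries. For HFD-Res it ranged from 377 (without HFD-NS replicate 16, and also without HFD-Res replicate 34) to 496, against 569. The genes shared by HFD-337 and HFD-Res ranged from 392 (without HFD-Res replicate 34) to 661, against 630. For HFD-337 the count moved back was 562 without SD-NS replicate 7, and the overlap with HFD-Res was 415 without HFD-NS replicate 13. The counts for HFD-338 stayed within 1.5 times (673 to 901 moved back, and 1283 to 1662 shared with HFD-337), and so did all of these counts with RLE size factors, no low-count filter and DESeq2.

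The level of Stk25 in HFD-338, 42.5% of SD-NS in CPM, was 50.5% in deposited TPM. In HFD-337 it was 34.6% and 34.1%, and in HFD-Res 83.0% and 89.4%. Each TPM library sums to the same total after counts are divided by length. A change in transcripts with many counts for their length therefore moves every other value, and whether this is the cause was not tested. The median of all genes in HFD-338 against HFD-NS was 0.000933 on the log2 scale with TMM and 0.0285 with RLE size factors. With recomputed TPM, which also brings another test and filter, it shifted to 0.12. Stk24 in HFD-338 against HFD-NS, -0.04 on that scale, changed sign with recomputed TPM (0.090, adjusted p = 0.66), which is less than this shift. Without 1 library it ranged from -0.085 to 0.0057 (without HFD-338 replicate 19, adjusted p = 0.984). It passed under none of the settings run.

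Tests of single named genes kept their direction and side of the threshold 8453 times. They kept the direction but no longer passed 332 times, of which 218 were without 1 library and 31 with recomputed TPM. They passed only under the alternative 4 times, 3 for Cyp7a1 and 1 for Thrb in HFD-Res, and reversed 2 times, both of them Stk24 above. Depth limits what can be seen for genes near the floor, such as Stk26, and for small changes, of which few were recovered in simulated data.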

Other observations

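The tests of exocrine pancreas and of the hepatocyte share below, and all 3 tests on female-biased genes, were chosen only after the result had been seen, as was the interval set around the correlation within hepatocyte lists.

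Marker lists of neutrophils, B and plasma cells, exocrine pancreas and skeletal muscle had 4, 4, 2 and 1 tested genes and were not tested as lists. Of their 15, 14, 13 and 11 genes, 4, 1, 3 and 0 were at 1 CPM or more in SD-NS liver. The B cell gene Cr2 was higher in HFD-338 than in HFD-NS (log2 fold change 3.11, adjusted p = 0.00229), a value of 4.86 without HFD-NS replicate 13. Pax5 was higher in HFD-337 (log2 fold change 2.15, adjusted p = 0.0128), a value of 3.41 without HFD-NS replicate 13, and did not pass without HFD-337 replicate 23 (1.72, adjusted p = 0.0625). The muscle gene Atp2a1 was higher in HFD-337 (log2 fold change 1.74, adjusted p = 0.00564). The pancreas gene Cela1 averaged 30.5 ± 17.4 CPM in HFD-337 and 6.70 ± 1.89 in HFD-338 (log2 fold change 2.18, SE 0.459, adjusted p = 0.00178). Among markers of T and NK cells, of which 6 of 18 were tested, Il7r was lower in HFD-337 than in HFD-338 (log2 fold change -2.19, adjusted p = 0.000145).

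Of the genes moved back towards SD-NS, 383 were shared by HFD-337 and HFD-338, 198 by HFD-337 and HFD-Res, 213 by HFD-338 and HFD-Res, and 96 by all 3. Over the 3711 genes called in HFD-NS against SD-NS, contrasts that share no library were set side by side. The change of HFD-NS against SD-NS had a correlation across genes of 0.15 with that of HFD-337 against HFD-338, 0.22 with that of HFD-337 against HFD-Res and -0.0795 with that of HFD-Res against HFD-338. Thinned to the smallest library's 3873903 counts, libraries held 14672 ± 99.2 genes with a count in SD-NS, 14968 ± 62.1 in HFD-NS, 15982 ± 124 in HFD-338, 15192 ± 319 in HFD-337 and 15050 ± 69.5 in HFD-Res. On the first principal component (32.9% of variance) HFD-337 replicate 23 lay at 38.55 and replicates 26 and 27 at 7.274 and 6.445. The quality weights of these 3 libraries were 0.572, 0.883 and 0.701.

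Genes with a long genomic span were lower in HFD-337 against HFD-NS, with a rank correlation of -0.34 between fold change and span over 13173 genes, against 0.0699 in HFD-338 and 0.00301 in HFD-Res. For each library's log2 CPM minus the mean of HFD-NS (of the other 2 for an HFD-NS library), the correlation with span was -0.296, -0.338 and -0.319 in HFD-337 replicates 23, 26 and 27, and -0.0729 to 0.124 in the other 12 libraries. For the fold change of HFD-337 against HFD-NS within 279 genes of hepatocyte lists it was -0.239 (95% interval -0.356 to -0.122). The interval comes from resampling genes as if they were independent and leaves out the spread between animals. The correlation itself argues against fewer endothelial and other non-hepatocyte cells as the whole cause, but only with a limit. In the same genes HFD-338 gave 0.0448 and HFD-Res 0.134, the latter without a trend over all genes. The value can therefore move in these lists for reasons other than span. With exon length, GC content (known for 97.6% of genes) and level held, -0.194 was left for span. With the others held in turn, GC content gave 0.174 and exon length -0.0501. The GC value was 0.151 in HFD-NS against SD-NS, -0.157 in HFD-338 and -0.0449 in HFD-Res. It was 0.259 in HFD-337 against HFD-338, where span gave -0.161. A trend with GC content is thus not particular to HFD-337. Bias from length or GC content may explain part of the span trend and cannot be told apart from the groups in these libraries. A loss of long transcripts specific to the agent in HFD-337 stays open, since HFD-338 gave -0.0265 for span with the others held. RNA quality, which was not tested, and a biological difference between the groups stay open too.

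Bile duct genes were higher in HFD-338 (median log2 fold change 3.41, quartiles 2.04 to 3.78), the most abundant being Spp1 (586 CPM, and 42.2 in HFD-NS) and Cdh1 (97.2 and 7.62). Exocrine pancreas is argued against: 13 acinar markers summed to 12.4 CPM in HFD-NS and 8.88 in HFD-338, a change of -3.47, with 10 at 0 in HFD-338 and Cela1 the most abundant at 6.7, while Spink1 rose by 36.4 CPM; a first version of this test had left out the level in HFD-NS. Endothelial markers, with a median of -0.727 (quartiles -1.01 to -0.358), argue against a lower share of hepatocytes in which all other cell types rose alike. Fibrosis genes and markers of lipid-associated macrophages rose in HFD-338. A lower share of hepatocytes with only some other cell types higher therefore stays open. In a further list of ductal genes the median was 2.51 with 17 of 21 higher and 1, Wwc1, lower, so more ductal cells or more ductal expression may explain the pattern, with Krt8 (0.08) and Krt18 (0.35) not passing. These cannot be parted from each other here, and a difference in the tissue sampled was not otherwise tested.

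Female-biased genes were higher in HFD-Res. Female animals are argued against, since Ddx3y, on the Y chromosome, was at 104% to 114% of the HFD-NS mean in its 3 libraries. Reads shared between near-identical gene copies are argued against as the whole cause by 4 genes outside those families that were higher with 0 lower of 11: Fmo2 (0.80), Cyp17a1 (3.10), Prom1 (3.50) and Cux2 (5.60). A shift away from male-type growth hormone signalling may be at work but is left open, because male-biased genes gave a camera adjusted p of 0.086.

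The 6 libraries of each comparison can be split in 10 ways, too few for a share under 0.05. With edgeR the real split gave 3711 genes in HFD-NS against SD-NS, 6220 in HFD-337 against HFD-NS, 4847 in HFD-338 against HFD-NS, 1709 in HFD-Res against HFD-NS, 7701 in HFD-337 against HFD-338 and 6283 in HFD-337 against HFD-Res. The highest of the other splits gave 0 in each, and 1 of 10 splits, the real one, gave as many. Every other split mixes libraries of the 2 groups compared, so real differences widen the spread within its groups and lower its count. A count of 0 there does not give the number of false calls between equal groups. At an unadjusted p under 0.05 the other splits reached 1037, 1053, 1012, 992, 1609 and 1265 genes, in that order, and the real ones 5165, 7082, 5971, 3371, 8313 and 7136. For gene lists called by camera, with the real split counted in, 7 splits gave as many as the real 9 in HFD-NS against SD-NS (highest other 16), 9 as many as 9 in HFD-337 against HFD-NS (18), and 4 as many as 19 in HFD-338 against HFD-NS (24). In HFD-Res against HFD-NS 1 split, the real one, gave 16 (highest other 14), in HFD-337 against HFD-338 6 gave at least 12 (21), and in HFD-337 against HFD-Res 9 gave at least 10 (16).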
